A study of Arabidopsis thaliana with 82 samples.

How the data were processed

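The files hold RNA-seq values for 82 libraries of hypocotyl tissue, 41 groups of 2 biological replicates that the labels call independent. Per the labels' protocols, RNA was extracted with RNeasy, stranded poly(A) libraries were made with TruSeq chemistry and 15 PCR cycles, and 11 to 12 barcoded samples were mixed at random into each of 7 lanes. The lane of a library is not given in the sources used here, so lanes could not be compared. The submitters' processing notes name cutadapt 1.8.1, Bowtie2 and the TAIR10 genome. The gene counter, the annotation release, the scaling method and whether counting used strand are not given in the sources used here. Antisense and overlapping genes, and genes with a near-identical copy, such as members of the light-harvesting and extensin families, are therefore uncertain.

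The values in both deposited tables are treated as a score, a normalised unit that the authors made per library, and in the second table also per gene length, and then rounded to whole numbers. Column sums of the first table ran from 10.05 to 19.7 M (1e6) and 75th percentiles from 373 to 398. That table was used, multiplied by 1 constant that makes the median column sum 1 M, and the result is written x. It lists 27416 genes, among them 88 of the chloroplast and 122 of the mitochondrion. Gene names come from the TAIR10.1 reference annotation, which matched 26719 identifiers; coordinates are of that reference.

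Depth was estimated from the steps between low values, which show what 1 read is worth, for 79 of 82 libraries, and a value of x of 1 then stands for 5.78 to 22.0 reads. Whole reads could not be recovered for nearly all genes, because the tables are rounded, so no count test was run. A gene under about x of 1 rests on few reads, and a level listed at 0 means below that, not absent. Estimated reads are PCR reads without molecular identifiers, so they overstate the number of independent molecules.

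Genes with x of at least 1 in at least 2 libraries were tested (20766). Tests ran on log2(x + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend), 1 mean per group and all 82 libraries in 1 fit with 41 residual degrees of freedom. The pseudocount of 1 makes a fold understate the change of low genes. Each contrast is the mean over 6, 12 and 24 h or over 120, 168 and 240 h of the difference within a time, with 6 libraries a side, and calls are at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The difference of differences between grafted and separated plants is an interaction contrast of the same fit. Single times have 2 libraries a side and describe the course. Deviations of same-numbered grafted tops and bottoms correlated at 0.148 to 0.506 at all 8 times, so by the values, as no label says it, replicate numbers pair these, and a count that the replicate block moves over 1.5 times has the block value beside it. Standard errors are limma's, from the shared spread (median prior degrees of freedom 5.00). Tables were read and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

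The windows, tests of the 18 contrasts, most alternatives, gene lists and the rule for named genes were chosen before the data were examined, and later choices are named as such. The 23 lists, with 402 members by gene identifier, cover auxin response, cytokinin response, ethylene, jasmonate, salicylic acid and defence, abscisic acid and drought, wound regeneration, rapid stress response, cambium, xylem and secondary wall, phloem, cell cycle, cell wall remodelling, sugar starvation, sugar-induced and anthocyanin genes, photosynthesis, nitrate response, phosphate starvation, hypoxia and the circadian clock. They also cover markers of root endodermis, hair and meristem, of the shoot meristem, and of shoot epidermis and guard cells, as tissue that a sample could hold besides hypocotyl. Lists were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01, and beside it with an estimated correlation. Adjustment ran over 23 lists in 18 contrasts, 414 tests. By fry, which asks whether a list moves 1 way on balance, 311 tests passed.

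Named genes are, per contrast, the 5 with the largest and the 5 with the smallest difference among called genes with a mean x of at least 5 and the same sign at 3 of 3 times. They are also up to 4 members of each called list with the smallest adjusted p in the direction of the list, and a fixed panel of 22 genes. Fewer are printed where comparisons share them.

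The tests were tried on simulated data. For grafted tops against bottoms at 6 to 24 h, with 20742 genes and 200 of them changed, 55 of 67 genes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered. Of 20542 unchanged genes 16 were called. A simulated list with 34 changed members was called, and 0 of 20 random lists were. Alternatives were other pseudocounts, filters, scalings (median of ratios, quantile), the length-normalised table, no trend, only the compared libraries, a replicate block, libraries left out 1 at a time, and, chosen after seeing the data, voom weights on estimated reads and 240 h alone.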

Results

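Poly(A) RNA was sequenced from the hypocotyl, the seedling stem below the cotyledons, of Arabidopsis thaliana Col-0 after cutting and grafting. The seedlings were 7 days old and grew in short days of 8 h light at 20 °C on agar without sucrose. One cotyledon was taken off every plant, and intact plants had no other operation. The other plants were also severed across the hypocotyl. The parts were then left apart (separated), or a top of one plant was aligned and joined with a bottom of another (grafted). Tissue above and below the wound was collected separately, giving separated tops, separated bottoms, grafted tops and grafted bottoms, with intact hypocotyls as the control. These 5 conditions were sampled at 6, 12, 24, 48, 72, 120, 168 and 240 h, and intact plants also at 0 h, which made 41 groups of 2 independent biological replicates and 82 libraries. The comparisons ask how tissue on either side of a wound comes to differ, how far that difference shrinks after joining, and which genes tell a joined part from an unjoined one.

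Depth was estimated at 7.55 to 20 M reads (M, 1e6; median 12.4 M) for 79 of 82 libraries. Medians of these by condition were 12.6 M in intact tissue, 15.5 in separated tops, 10.5 in separated bottoms, 13 in grafted tops and 12.1 in grafted bottoms. Replicates correlated across genes at r = 0.971 to 0.993 on the log2 scale. The 10 genes with the highest values took 3.01 to 11.1% of a library. Their median share was 9.51% in separated bottoms, 8.00% in intact tissue, 5.64% in grafted bottoms, 4.23% in grafted tops and 3.81% in separated tops. Log2 differences below are means over 6 to 24 h or over 120 to 240 h, with 6 libraries on each side and the standard error after ±. A level is a mean ± SD over the 6 libraries of a window, in units where a median library sums to 1 M. Genes given as called had 1 direction at 3 of 3 times (not checked against 0 h). Gene list results give how many measured members passed the test in each direction, the median log2 difference and the adjusted p of the list test. Of 184 list calls, 14 also passed with an estimated correlation, and they are those whose second p lies under 0.05.

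Separated tops and bottoms were compared to see how the parts of a severed hypocotyl diverge when they are not joined. At 6 to 24 h auxin-response, cambium and cell division genes were higher in the tops, and carbon starvation genes were higher in the bottoms. IAA5 (AT1G15580), an early auxin-response gene, stood at 26.0 ± 9.86 in separated tops and was listed at 0 in all 6 separated bottoms. PXY (AT5G61480), the cambial receptor kinase, was 28.9-fold higher in tops (4.85 ± 0.17, adjusted p = 1.1e-28), and ASN1 (AT3G47340), a starvation-induced asparagine synthetase, was 44.9-fold lower (-5.49 ± 0.41). Among the largest differences by the naming rule were HAT2 (AT5G47370, 6.79 ± 0.20), an auxin-induced homeobox gene, AT1G53070 (6.68 ± 0.19) and XTH20 (AT5G48070, 5.97 ± 0.23), a cell wall transglycosylase. On the other side stood BGAL4 (AT5G56870, -6.92 ± 0.48), a beta-galactosidase, GLYI7 (AT1G80160, -6.29 ± 0.25) and BT2 (AT3G48360, -6.27 ± 0.52).

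Among 20 auxin response genes, 19 were higher and 1 was lower (median 4.08, adjusted p = 3.6e-09, adjusted p = 0.036 with estimated correlation), led by IAA19 (AT3G15540, 5.64 ± 0.16) and the efflux carrier PIN3 (AT1G70940, 4.63 ± 0.15). 15 of 18 cambium genes were higher and 3 were not called (median 2.16, adjusted p = 2.7e-07, adjusted p = 0.068 with estimated correlation), with RUL1 (AT5G05160, 4.12 ± 0.10), ANT (AT4G37750, 4.84 ± 0.13) and HB8 (AT4G32880, 4.72 ± 0.14) among them. Of the 30 xylem and secondary wall genes 27 were higher, 2 were lower and 1 was not called (median 1.92, adjusted p = 3.5e-06, adjusted p = 0.17 with estimated correlation), including the thermospermine synthase ACL5 (AT5G19530, 4.82 ± 0.22) and the secondary wall cellulose synthase CESA8 (AT4G18780, 3.84 ± 0.27). Among 29 cell cycle genes, 28 were higher and 1 was not called (median 1.37, adjusted p = 7.3e-07, adjusted p = 0.25 with estimated correlation). 14 of 15 sugar-induced and anthocyanin genes were higher and 1 was not called (median 2.88, adjusted p = 0.0023, adjusted p = 0.41 with estimated correlation). Of the 22 sugar starvation genes 21 were lower and 1 was not called (median -3.89, adjusted p = 9.5e-11, adjusted p = 0.24 with estimated correlation), and all 26 photosynthesis genes were lower (median -2.04, adjusted p = 1.5e-10, adjusted p = 0.36 with estimated correlation). Among 11 cytokinin response genes, 7 were lower, 2 were higher and 2 were not called (median -1.35, adjusted p = 0.015, adjusted p = 0.30 with estimated correlation), with the type-A response regulators ARR4 (AT1G10470, -4.55 ± 0.13) and ARR5 (AT3G48100, -4.00 ± 0.21) lower. The lists called were 10 of 23. With adjustment over the list alone, member counts given here did not move. Limma called 14960 of 20766 genes, 8395 higher in tops and 6565 lower, and 6479 of them differed at least 2-fold.

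By 120 to 240 h the separated parts differed at 16529 genes, 10252 of them higher in tops and 6277 lower, with 8383 at least 2-fold. Among the genes lowest in separated tops were LHCB2.3 (AT3G27690, -8.63 ± 0.32) and LHB1B1 (AT2G34430, -8.48 ± 0.43), light-harvesting proteins, and CA1 (AT3G01500, -7.89 ± 0.41), a carbonic anhydrase, none of them in the photosynthesis list. LHB1B1 stood at 10.5 ± 10.0 in tops and 2997 ± 1354 in bottoms. DR4 (AT1G73330, 9.14 ± 0.39), MLP34 (AT1G70850, 9.05 ± 0.25) and CYP81F4 (AT4G37410, 8.92 ± 0.21), an enzyme of indole glucosinolate synthesis, were among the highest in tops, and NAS3 (AT1G09240, -7.14 ± 0.21), a nicotianamine synthase, was lower. Genes of root cells were also higher in separated tops at this stage. The 15 root marker genes were all higher (median 2.32, adjusted p = 2.0e-05, adjusted p = 0.12 with estimated correlation), with the iron transporter IRT1 (AT4G19690, 2.32 ± 0.08). Their median difference was 3.92 at 48 h, 4.25 at 120 h and 0.30 at 240 h.

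All 26 photosynthesis genes were lower (median -4.47, adjusted p = 1.2e-16, adjusted p = 0.23 with estimated correlation). 17 of 18 cambium genes were higher and 1 was lower (median 3.13, adjusted p = 4.4e-06, adjusted p = 0.095 with estimated correlation), with WOX4 (AT1G46480, 2.99 ± 0.16), a cambium homeobox gene, at 31 ± 17.8 in tops and 2.44 ± 0.973 in bottoms. Of the 30 xylem and secondary wall genes 28 were higher, 1 was lower and 1 was not called (median 2.71, adjusted p = 1.9e-06, adjusted p = 0.16 with estimated correlation), among them CESA7 (AT5G17420, 3.22 ± 0.24) and VND7 (AT1G71930, 3.11 ± 0.14), a vessel NAC factor. Among 23 phloem genes, 21 were higher and 2 were lower (median 2.1, adjusted p = 1.7e-04, adjusted p = 0.21 with estimated correlation), including APL (AT1G79430, 1.76 ± 0.10) and BAM3 (AT4G20270, 4.11 ± 0.13). 27 of 29 cell cycle genes were higher and 2 were not called (median 2.48, adjusted p = 1.3e-06, adjusted p = 0.26 with estimated correlation). Of the 20 auxin response genes 18 were higher and 2 were not called (median 1.77, adjusted p = 0.0018, adjusted p = 0.26 with estimated correlation), and among 22 sugar starvation genes, 18 were lower, 1 was higher and 3 were not called (median -1.57, adjusted p = 5.3e-04, adjusted p = 0.54 with estimated correlation). Member counts given here, adjusted over the list alone, did not move. 12 of the 23 lists were called. The median of all genes was 0.25 higher in tops, and quantile normalisation brought it to 0.02. The share of calls that were higher in tops was 62.0%, and 51.3% under quantile normalisation.

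Grafted tops and bottoms show how far the parts still differ once they are joined. At 6 to 24 h they differed at 13462 genes, 7857 higher in tops and 5605 lower, with 4145 at least 2-fold. Carbon starvation genes were far higher in grafted bottoms, where ASN1 stood at 3113 ± 1097 against 82.0 ± 46.9 in grafted tops (-5.36 ± 0.41, adjusted p = 1.7e-15). BGAL4 (-7.48 ± 0.48), GAT1_2.1 (AT1G15040, -6.90 ± 0.37) and DIN2 (AT3G60140, -6.32 ± 0.41), a dark-induced glucosidase, had the largest differences in that direction with a known name. Sugar-induced genes went the other way, with APL3 (AT4G39210, 2.95 ± 0.33), a subunit of ADP-glucose pyrophosphorylase, and GPT2 (AT1G61800, 3.2 ± 0.50), a glucose-6-phosphate translocator. Among the highest in tops were MLP423 (AT1G24020, 5.61 ± 0.29), LTL1 (AT3G04290, 5.37 ± 0.26), GH9B8 (AT2G32990, 5.02 ± 0.30) and PGDH (AT1G17745, 4.88 ± 0.27). IAA5 stood at 12.3 ± 6.38 in grafted tops and 3.59 ± 1.11 in grafted bottoms.

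21 of 22 sugar starvation genes were lower and 1 was not called (median -3.73, adjusted p = 2.6e-14, adjusted p = 0.17 with estimated correlation), with the amino acid catabolism genes IVD (AT3G45300, -3.97 ± 0.16) and GDH1 (AT5G18170, -3.15 ± 0.17). Of the 15 sugar-induced and anthocyanin genes 14 were higher and 1 was not called (median 2.51, adjusted p = 2.3e-04, adjusted p = 0.30 with estimated correlation), including the beta-amylase BAM5 (AT4G15210, 2.25 ± 0.21). The 26 photosynthesis genes were all lower (median -1.77, adjusted p = 1.1e-12, adjusted p = 0.29 with estimated correlation), among them the Rubisco activase RCA (AT2G39730, -2.43 ± 0.18). Among 30 xylem and secondary wall genes, 28 were higher, 1 was lower and 1 was not called (median 1.62, adjusted p = 6.5e-07, adjusted p = 0.14 with estimated correlation), with VND1 (AT2G18060, 1.71 ± 0.14) and VND7 (1.67 ± 0.14). 24 of 29 cell cycle genes were higher and 5 were not called (median 0.89, adjusted p = 2.1e-05, adjusted p = 0.32 with estimated correlation), where the replication helicase subunit MCM6 (AT5G44635, 2.02 ± 0.15) was higher. Of the 18 cambium genes 12 were higher and 6 were not called (median 0.72, adjusted p = 0.0038, adjusted p = 0.28 with estimated correlation), with ANT (1.97 ± 0.13), PXY (1.74 ± 0.17) and CYCD3;1 (AT4G34160, 1.60 ± 0.14). Among 20 auxin response genes, 13 were higher, 2 were lower and 5 were not called (median 1.18, adjusted p = 0.014, adjusted p = 0.38 with estimated correlation), with IAA19 (2.11 ± 0.16) and HAT2 (2.06 ± 0.20). 10 of 14 circadian clock genes were lower, 1 was higher and 3 were not called (median -0.87, adjusted p = 0.013, adjusted p = 0.24 with estimated correlation). Of the 16 ethylene genes 9 were lower, 1 was higher and 6 were not called (median -0.65, adjusted p = 0.025, adjusted p = 0.48 with estimated correlation), and under quantile normalisation it was not called (adjusted p = 0.0503; 0.022 to 0.48 over the alternatives tried). In all, 10 of the 23 lists were called. The counts given here, adjusted over the list alone, moved only for cell cycle (25 higher, 0 lower).

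At 120 to 240 h grafted tops and bottoms differed at 4904 genes, 2576 higher in tops and 2328 lower. Among the genes with the largest differences were BGLU21 (AT1G66270, 3.61 ± 0.22), PDF1 (AT2G42840, 2.78 ± 0.27), an epidermal gene, and the malate transporter ALMT1 (AT1G08430, 2.23 ± 0.18) in tops. CYP94B3 (AT3G48520, -3.27 ± 0.25), which inactivates jasmonate, CYP79F1 (AT1G16410, -3.13 ± 0.44), an enzyme of aliphatic glucosinolate synthesis, and the nitrate transporter NRT1.5 (AT1G32450, -2.72 ± 0.23) were lower there. The difference in carbon starvation genes had gone: the list median was -3.68 at 6 h, -0.74 at 72 h and 0.05 at 120 h. Some defence and rapid stress genes were higher below the junction, and some auxin and cambium genes above it, and none of these 4 lists passed with an estimated correlation. Among 12 rapid stress response genes, 10 were lower and 2 were not called (median -0.99, adjusted p = 2.9e-10, adjusted p = 0.10 with estimated correlation), with WRKY40 (AT1G80840, -2.35 ± 0.29) and ZAT12 (AT5G59820, -1.25 ± 0.21). 5 of 10 salicylic acid and defence genes were lower and 5 were not called (median -0.52, adjusted p = 0.0067, adjusted p = 0.25 with estimated correlation), where ICS1 (AT1G74710, -0.59 ± 0.12), the isochorismate synthase of salicylic acid synthesis, was lower.

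Of the 23 jasmonate genes 10 were lower, 1 was higher and 12 were not called (median -0.53, adjusted p = 3.5e-06, adjusted p = 0.26 with estimated correlation), with LOX4 (AT1G72520, -2.15 ± 0.29) and JAZ8 (AT1G30135, -2.32 ± 0.23). Among 26 photosynthesis genes, 23 were lower and 3 were not called (median -0.64, adjusted p = 3.8e-10, adjusted p = 0.37 with estimated correlation). 10 of 20 auxin response genes were higher and 10 were not called (median 0.41, adjusted p = 6.8e-04, adjusted p = 0.23 with estimated correlation), with LBD16 (AT2G42430, 1.23 ± 0.15) and GH3.3 (AT2G23170, 1.35 ± 0.27). Of the 18 cambium genes 7 were higher and 11 were not called (median 0.29, adjusted p = 0.0041, adjusted p = 0.28 with estimated correlation), led by PEAR1 (AT2G37590, 0.72 ± 0.17) and TMO6 (AT5G60200, 0.62 ± 0.16). Among 5 shoot meristem marker genes, 2 were higher and 3 were not called (median 0.35, adjusted p = 0.0078, adjusted p = 0.068 with estimated correlation), which were STM (AT1G62360, 2.3 ± 0.18) and KNAT6 (AT1G23380, 0.47 ± 0.09), shoot meristem homeobox genes. 9 of the 23 lists were called. Adjusted over the list alone, the member counts given here moved only for rapid stress response (0 higher, 11 lower), jasmonate (1 higher, 11 lower), photosynthesis (0 higher, 24 lower), cambium (9 higher, 0 lower) and shoot meristem markers (3 higher, 0 lower). Per time, grafted tops and bottoms differed at 9291 genes at 6 h, 10217 at 24 h, 5490 at 72 h and 566 at 240 h (935 with the replicate block). Separated parts differed at 10613, 12712, 14508 and 11931 genes at those times.

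**Figure D1:**
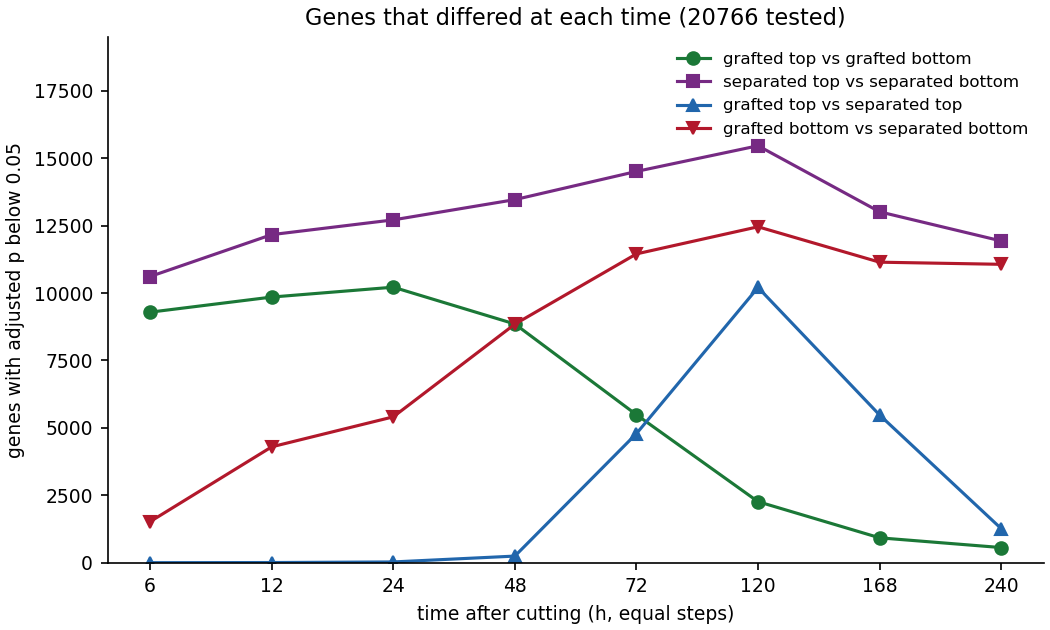
Genes called at each time (y axis, number of 20766 tested; x axis, hours after cutting in equal steps) for 4 comparisons of 2 libraries a side. Grafted parts fell from 10217 genes at 24 h to 566 at 240 h (935 with the replicate block), and grafted against separated tops peaked at 10206 at 120 h.

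Whether the top-bottom difference itself differed between grafted and separated plants was tested gene by gene as a difference of differences, (top minus bottom in grafted) minus (top minus bottom in separated). At 6 to 24 h auxin and cambium genes had the clearest change. Their lead in tops was smaller in grafted plants. IAA2 (AT3G23030, -5.56 ± 0.28), IAA1 (AT4G14560, -4.94 ± 0.29) and HAT2 (-4.72 ± 0.28), early auxin-response genes, PIN3 (-4.68 ± 0.22) and the peptide gene RGF9 (AT5G64770, -5.29 ± 0.33) had the most negative values. Among the most positive were AT1G29090 (4.42 ± 0.27), GPAT1 (AT1G06520, 3.48 ± 0.25) and ARR4 (3.47 ± 0.19). PXY changed by -3.11 ± 0.24 (adjusted p = 8.6e-15). 15 of 20 auxin response genes were lower and 5 were not called (median -2.43, adjusted p = 2.9e-29, adjusted p = 2.0e-05 with estimated correlation). Of the 18 cambium genes 13 were lower and 5 were not called (median -1.48, adjusted p = 1.6e-18, adjusted p = 4.8e-04 with estimated correlation). ASN1 and GPT2, which respond to sugar, had values of 0.13 ± 0.59 (adjusted p = 0.93) and -0.23 ± 0.71 (adjusted p = 0.89).

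Among 16 wound regeneration genes, 9 were lower, 4 were higher and 3 were not called (median -1.36, adjusted p = 4.4e-04, adjusted p = 0.16 with estimated correlation), with ANAC071 (AT4G17980, -3.68 ± 0.22), a wound-induced NAC factor of cut stems, ERF115 (AT5G07310, -2.47 ± 0.25) and XTH20 (-3.51 ± 0.32). 9 of 12 rapid stress response genes were lower and 3 were not called (median -1.56, adjusted p = 7.0e-06, adjusted p = 0.25 with estimated correlation). Of the 11 cytokinin response genes 6 were higher and 5 were not called (median 0.87, adjusted p = 2.1e-05, adjusted p = 0.082 with estimated correlation). Among 23 jasmonate genes, 7 were higher, 1 was lower and 15 were not called (median 0.85, adjusted p = 1.0e-04, adjusted p = 0.35 with estimated correlation). 9 of 23 phloem genes were lower and 14 were not called (median -0.53, adjusted p = 2.8e-06, adjusted p = 0.10 with estimated correlation), and of the 29 cell cycle genes 11 were lower and 18 were not called (median -0.56, adjusted p = 3.0e-06, adjusted p = 0.27 with estimated correlation). Among 26 photosynthesis genes, 2 were higher and 24 were not called (median 0.29, adjusted p = 0.029, adjusted p = 0.77 with estimated correlation), a direction that ended under quantile normalisation, where the median was 0.00 and adjusted p = 0.96, with 0.022 to 0.96 over the alternatives. Neither sugar list was called: 2 of 22 sugar starvation genes were higher and 20 were not called (median 0.13, adjusted p = 0.23, adjusted p = 0.84 with estimated correlation), and of the 15 sugar-induced and anthocyanin genes 1 was lower and 14 were not called (median -0.23, adjusted p = 0.72, adjusted p = 0.92 with estimated correlation). The lists called were 13 of 23. With adjustment over the list alone, member counts given here moved only for auxin response (0 higher, 18 lower), cambium (0 higher, 14 lower), jasmonate (8 higher, 1 lower), phloem (0 higher, 10 lower), photosynthesis (0 higher, 0 lower) and sugar-induced and anthocyanin (0 higher, 0 lower). The test called 4572 genes, 2169 with a more positive difference in grafted plants and 2403 with a more negative one.

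**Figure D2:**
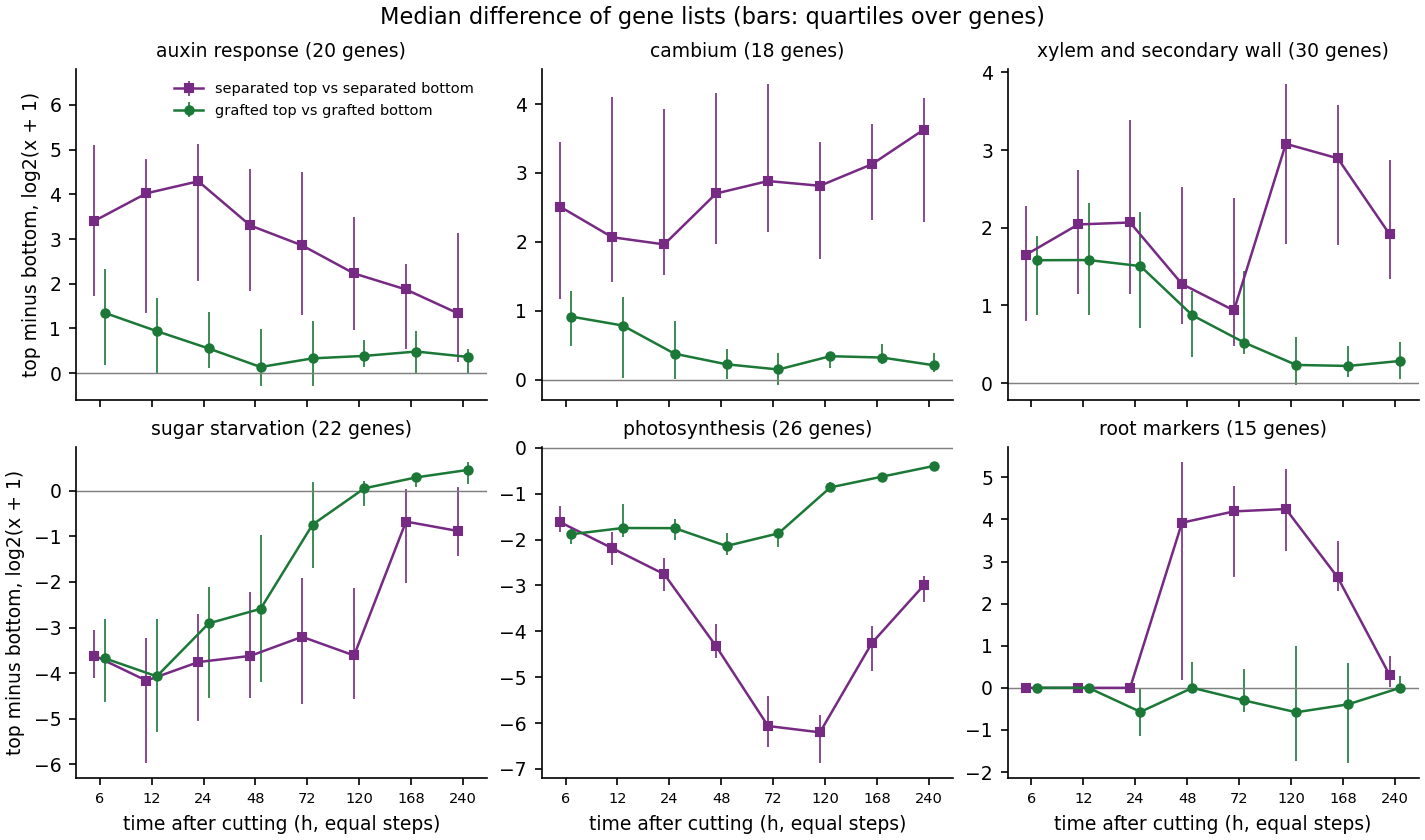
Median top-minus-bottom difference of 6 gene lists in log2(x + 1), with quartiles over genes as bars, against hours after cutting in equal steps, for separated (purple) and grafted (green) plants. The auxin response median at 48 h was 0.14 in grafted and 3.3 in separated plants, and that of sugar starvation -2.59 and -3.62.

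Per time, the difference of differences was called for 570 genes at 6 h, 2732 at 24 h, 10868 at 72 h and 12832 at 120 h. The genes called between separated parts at 6 to 24 h, 8395 higher in tops and 6565 higher in bottoms, were followed over time as the median top-minus-bottom difference of the first set minus that of the second. The choice was made on the separated parts, which raises their early values. In grafted plants this distance was 1.2 at 6 h, 1.26 at 24 h, 0.97 at 48 h and 0.27 at 72 h. In separated plants it was 1.52, 1.96, 1.95 and 1.99. At 240 h the values were 0.059 and 0.99.

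**Figure D3:**
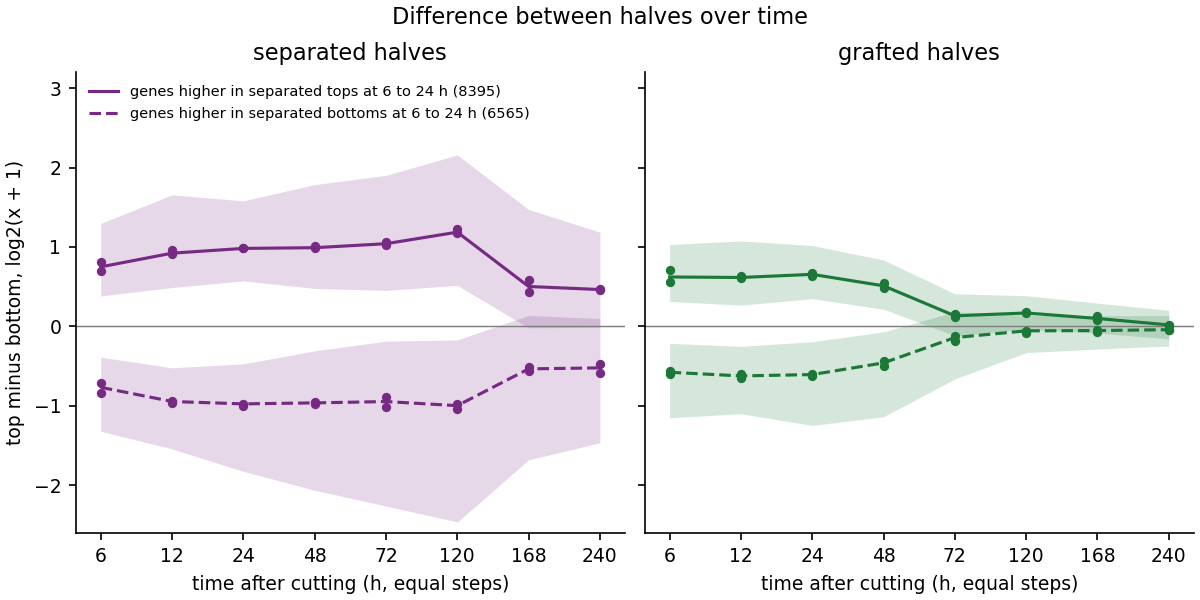
Median top-minus-bottom difference in log2(x + 1) (lines; shading, quartiles over genes; points, the 2 replicates) against hours after cutting in equal steps, for 8395 genes chosen as higher in separated tops and 6565 in separated bottoms. The lines of grafted parts draw closer between 48 and 72 h, from a distance of 0.97 to 0.27.

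At 120 to 240 h the test of the difference of differences called 14463 genes, 5823 more positive in grafted plants and 8640 more negative, and 8996 at 240 h alone, a restriction chosen after seeing the data. LHCB2.3 (7.36 ± 0.45), LHB1B1 (6.82 ± 0.60) and CA1 (6.75 ± 0.58) were positive, and MLP34 (-9.46 ± 0.35), NRT1.5 (-8.89 ± 0.33), CYP81F4 (-8.33 ± 0.29) and the amino acid permease AAP2 (AT5G09220, -8.21 ± 0.35) were negative. All 26 photosynthesis genes were higher (median 3.87, adjusted p = 1.2e-16, adjusted p = 0.23 with estimated correlation). Among 18 cambium genes, 16 were lower, 1 was higher and 1 was not called (median -2.84, adjusted p = 1.6e-06, adjusted p = 0.082 with estimated correlation), and 28 of 30 xylem and secondary wall genes were lower and 2 were not called (median -2.42, adjusted p = 2.3e-06, adjusted p = 0.17 with estimated correlation). Of the 23 phloem genes 20 were lower, 1 was higher and 2 were not called (median -1.83, adjusted p = 1.1e-04, adjusted p = 0.19 with estimated correlation), and among 29 cell cycle genes, 26 were lower and 3 were not called (median -2.12, adjusted p = 8.3e-07, adjusted p = 0.26 with estimated correlation). 15 of 20 auxin response genes were lower and 5 were not called (median -1.09, adjusted p = 0.0092, adjusted p = 0.35 with estimated correlation), and of the 22 sugar starvation genes 16 were higher, 1 was lower and 5 were not called (median 2.01, adjusted p = 3.9e-04, adjusted p = 0.53 with estimated correlation). Root markers moved with these groups: among 15 root marker genes, 14 were lower and 1 was not called (median -2.47, adjusted p = 2.6e-06, adjusted p = 0.092 with estimated correlation). Member counts given here, adjusted over the list alone, moved only for phloem (1 higher, 21 lower). 12 of the 23 lists were called. The median of all genes was -0.18, and 0.02 under quantile normalisation. The share of positive calls was 40.3%, and 50.4% under that scaling.

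Grafted tops were compared with separated tops to find genes that respond to joining above the wound. At 6 to 24 h the auxin-response genes were lower in grafted tops, though few genes differed. ACS4 (AT2G22810, -1.08 ± 0.10), ACS8 (AT4G37770, -1.12 ± 0.16), auxin-induced genes of ethylene synthesis, IAA5 (-1.08 ± 0.13) and IAA19 (-1.10 ± 0.16) fell by about the same amount. IAA5 stood at 12.3 ± 6.38 in grafted tops and 26.0 ± 9.86 in separated tops. Among the largest differences were KDR (AT1G26945, -2.2 ± 0.26), AT5G02760 (-1.48 ± 0.27), AT2G43590 (-1.40 ± 0.30) and RGF6 (AT4G16515, -1.24 ± 0.17). Of the 7 genes that were higher in grafted tops, ARR4 (1.02 ± 0.13) had the largest difference by the naming rule, followed by CYP81F4 (0.87 ± 0.21) and JR1 (AT3G16470, 0.64 ± 0.15). The calls of 4 of these genes were weak. With only the compared libraries in the fit, adjusted p was 0.14 for AT5G02760, 0.27 for AT2G43590, 0.451 for CYP81F4 and 0.188 for JR1. The last 3 were also lost with a pseudocount of 0.25 (adjusted p = 0.352, 0.137 and 0.0672) and with any of several single libraries left out (up to 0.162, 0.513 and 0.379). 9 of 20 auxin response genes were lower and 11 were not called (median -0.71, adjusted p = 3.9e-48, adjusted p = 1.2e-07 with estimated correlation).

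Limma called 72 genes, 7 higher in grafted tops and 65 lower, out of 20766. This count depended on the settings: 41 genes were called with a pseudocount of 0.25, 43 when only the compared libraries were fitted, and 44 to 71 when 1 library was left out, the lowest without replicate 2 of the grafted tops at 24 h. Of the 11 cytokinin response genes 1 was higher and 10 were not called (median 0.12, adjusted p = 0.029, adjusted p = 0.37 with estimated correlation). The other 4 called lists, jasmonate, nitrate response, photosynthesis and shoot meristem markers, had medians of 0.21, 0.17, 0.12 and 0.23 (adjusted p = 0.37, adjusted p = 0.15, adjusted p = 0.70 and adjusted p = 0.068 with an estimated correlation). In all, 6 of the 23 lists were called. The counts given here, adjusted over the list alone, moved only for auxin response (0 higher, 16 lower).

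At 120 to 240 h grafted and separated tops differed at 10230 genes, 4041 higher in grafted tops and 6189 lower, and at 1269 genes at 240 h alone, a restriction chosen after seeing the data. LHCB2.3 (4.2 ± 0.32), NEET (AT5G51720, 3.78 ± 0.23) and CA1 (3.62 ± 0.41), none of them in the photosynthesis list, were among the highest in grafted tops. CYP705A5 (AT5G47990, -5.45 ± 0.23) and THAS1 (AT5G48010, -5.24 ± 0.26), genes of the thalianol pathway, and MLP328 (AT2G01520, -4.62 ± 0.12) were among the lowest. The 26 photosynthesis genes were all higher (median 2.28, adjusted p = 1.6e-25, adjusted p = 0.12 with estimated correlation). Among 18 cambium genes, 12 were higher, 1 was lower and 5 were not called (median 0.54, adjusted p = 1.5e-04, adjusted p = 0.17 with estimated correlation), with ANT (1.2 ± 0.13), LBD4 (AT1G31320, 1.23 ± 0.17) and WOX4 (1.08 ± 0.16). 7 of 23 phloem genes were higher and 16 were not called (median 0.21, adjusted p = 0.031, adjusted p = 0.45 with estimated correlation), with CVP2 (AT1G05470, 0.78 ± 0.15) and SEOR1 (AT3G01680, 1.3 ± 0.25). Of the 29 cell cycle genes 22 were lower and 7 were not called (median -0.53, adjusted p = 0.0048, adjusted p = 0.52 with estimated correlation). Among 5 shoot meristem marker genes, 4 were higher and 1 was not called (median 0.52, adjusted p = 0.019, adjusted p = 0.10 with estimated correlation), with the boundary gene CUC3 (AT1G76420, 1.68 ± 0.12). Root markers moved the other way: 8 of 15 root marker genes were lower, 1 was higher and 6 were not called (median -0.55, adjusted p = 4.5e-04, adjusted p = 0.21 with estimated correlation), with IRT1 (-2.07 ± 0.08), and a median of -1.64 at 120 h and 0.11 at 240 h. 9 of the 23 lists were called. Adjusted over the list alone, the member counts given here moved only for root endodermis, hair and meristem markers (1 higher, 9 lower).

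Below the wound, grafted bottoms were compared with separated bottoms. At 6 to 24 h auxin-response and cambium genes were higher in grafted bottoms. IAA2 (4.86 ± 0.20), IAA1 (4.22 ± 0.21), PIN3 (4.60 ± 0.15) and RGF9 (4.78 ± 0.24) had the largest differences with a known name, and GPAT1 (-3.43 ± 0.18) was among the lowest. IAA5 stood at 3.59 ± 1.11 in grafted bottoms and was listed at 0 in the 6 separated bottoms. PXY was 9.96-fold higher (3.32 ± 0.17, adjusted p = 1.6e-21) and ANAC071 10.1-fold higher (3.34 ± 0.16). Of the 20 auxin response genes 13 were higher and 7 were not called (median 1.54, adjusted p = 1.0e-15, adjusted p = 0.0020 with estimated correlation), and among 18 cambium genes, 14 were higher and 4 were not called (median 1.58, adjusted p = 1.6e-18, adjusted p = 4.8e-04 with estimated correlation). 9 of 16 wound regeneration genes were higher, 4 were lower and 3 were not called (median 1.33, adjusted p = 0.0015, adjusted p = 0.21 with estimated correlation), with ERF115 (2.31 ± 0.18) higher and RAP2.6L (AT5G13330, -2.57 ± 0.18) in the opposite direction. Of the 22 sugar starvation genes 3 were lower, 1 was higher and 18 were not called (median -0.37, adjusted p = 0.043, adjusted p = 0.73 with estimated correlation), and under quantile normalisation it was not called (adjusted p = 0.42; 0.025 to 0.73 over the alternatives tried); ASN1 had -0.63 ± 0.41 (adjusted p = 0.25).

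Among 29 cell cycle genes, 22 were higher and 7 were not called (median 0.67, adjusted p = 1.1e-08, adjusted p = 0.20 with estimated correlation), and 15 of 23 phloem genes were higher and 8 were not called (median 0.61, adjusted p = 1.4e-07, adjusted p = 0.068 with estimated correlation). Of the 21 cell wall remodelling genes 10 were higher, 2 were lower and 9 were not called (median 0.32, adjusted p = 0.020, adjusted p = 0.29 with estimated correlation), with the transglycosylase XTH9 (AT4G03210, 2.90 ± 0.21) and the expansin EXPA5 (AT3G29030, 2.01 ± 0.25). Among 12 rapid stress response genes, 9 were higher and 3 were not called (median 1.68, adjusted p = 1.9e-06, adjusted p = 0.23 with estimated correlation). 11 of 23 jasmonate genes were lower, 1 was higher and 11 were not called (median -0.58, adjusted p = 0.0027, adjusted p = 0.48 with estimated correlation), and of the 11 cytokinin response genes 6 were lower and 5 were not called (median -0.75, adjusted p = 1.2e-04, adjusted p = 0.11 with estimated correlation). The lists called were 12 of 23. With adjustment over the list alone, member counts given here moved only for wound regeneration (9 higher, 5 lower), sugar starvation (0 higher, 3 lower), cell cycle (24 higher, 0 lower), phloem (16 higher, 0 lower), cell wall remodelling (10 higher, 3 lower) and jasmonate (1 higher, 12 lower). Limma called 7189 genes, 3634 higher in grafted bottoms and 3555 lower. Of the 72 genes called between grafted and separated tops, 38 were lower in grafted tops and higher in grafted bottoms than in their separated counterparts, against 11.4 for independent lists (Fisher's exact test, 2-sided p = 1.4e-13), and 19 with a pseudocount of 0.25. Genes are not independent replicates in that test. These comparisons share no library. Lower on both sides were 4 genes, against 11.1 for independent lists (Fisher's exact p = 0.0193). Higher on both sides were 0 called genes, against 1.23 (Fisher's exact p = 0.614). At limma's unadjusted p under 0.05 in both, 83 genes were, fewer than in other direction pairs (102 to 215).

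Late grafted and separated bottoms, at 120 to 240 h, differed at 14582 genes, 7391 higher in grafted bottoms and 7191 lower, with 6337 at least 2-fold. Vascular genes were higher in grafted bottoms: WOX4 (3.79 ± 0.16) stood at 45.2 ± 4.69 in grafted and 2.44 ± 0.973 in separated bottoms. The largest differences with a known name were MLP34 (8.67 ± 0.25), NRT1.5 (8.44 ± 0.23), NAS1 (AT5G04950, 8.34 ± 0.29), and, lower, UPI (AT5G43580, -6.12 ± 0.29) and NAS3 (-5.48 ± 0.21). Among 18 cambium genes, 16 were higher, 1 was lower and 1 was not called (median 3.47, adjusted p = 4.2e-10, adjusted p = 0.021 with estimated correlation). 28 of 30 xylem and secondary wall genes were higher, 1 was lower and 1 was not called (median 2.53, adjusted p = 6.6e-09, adjusted p = 0.083 with estimated correlation), and of the 23 phloem genes 21 were higher, 1 was lower and 1 was not called (median 1.96, adjusted p = 1.3e-07, adjusted p = 0.068 with estimated correlation). Among 29 cell cycle genes, 26 were higher and 3 were not called (median 1.76, adjusted p = 1.1e-06, adjusted p = 0.26 with estimated correlation), and 14 of 20 auxin response genes were higher and 6 were not called (median 1.67, adjusted p = 5.0e-04, adjusted p = 0.22 with estimated correlation). Of the 22 sugar starvation genes 17 were lower, 1 was higher and 4 were not called (median -1.61, adjusted p = 5.9e-04, adjusted p = 0.54 with estimated correlation), where ASN1 fell by 4.04 ± 0.41. All 26 photosynthesis genes were lower (median -1.66, adjusted p = 1.2e-07, adjusted p = 0.45 with estimated correlation), and under quantile normalisation it was not called (adjusted p = 0.41; 4.0e-08 to 0.45 over the alternatives tried).

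Among 23 jasmonate genes, 15 were higher, 5 were lower and 3 were not called (median 1.52, adjusted p = 0.020, adjusted p = 0.58 with estimated correlation), with the synthesis genes AOC3 (AT3G25780, 4.82 ± 0.24), AOS (AT5G42650, 3.49 ± 0.22) and OPR3 (AT2G06050, 2.89 ± 0.20). 10 of 12 rapid stress response genes were higher, 1 was lower and 1 was not called (median 1.54, adjusted p = 0.0081, adjusted p = 0.51 with estimated correlation). Root markers moved with the vascular groups: of the 15 root marker genes 9 were higher and 6 were not called (median 1.05, adjusted p = 0.0026, adjusted p = 0.27 with estimated correlation), with the Casparian strip gene CASP1 (AT2G36100, 5.17 ± 0.22), and medians of 2.13 at 120 h and 0.11 at 240 h. Member counts given here, adjusted over the list alone, did not move. 14 of the 23 lists were called.

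**Figure D4:**
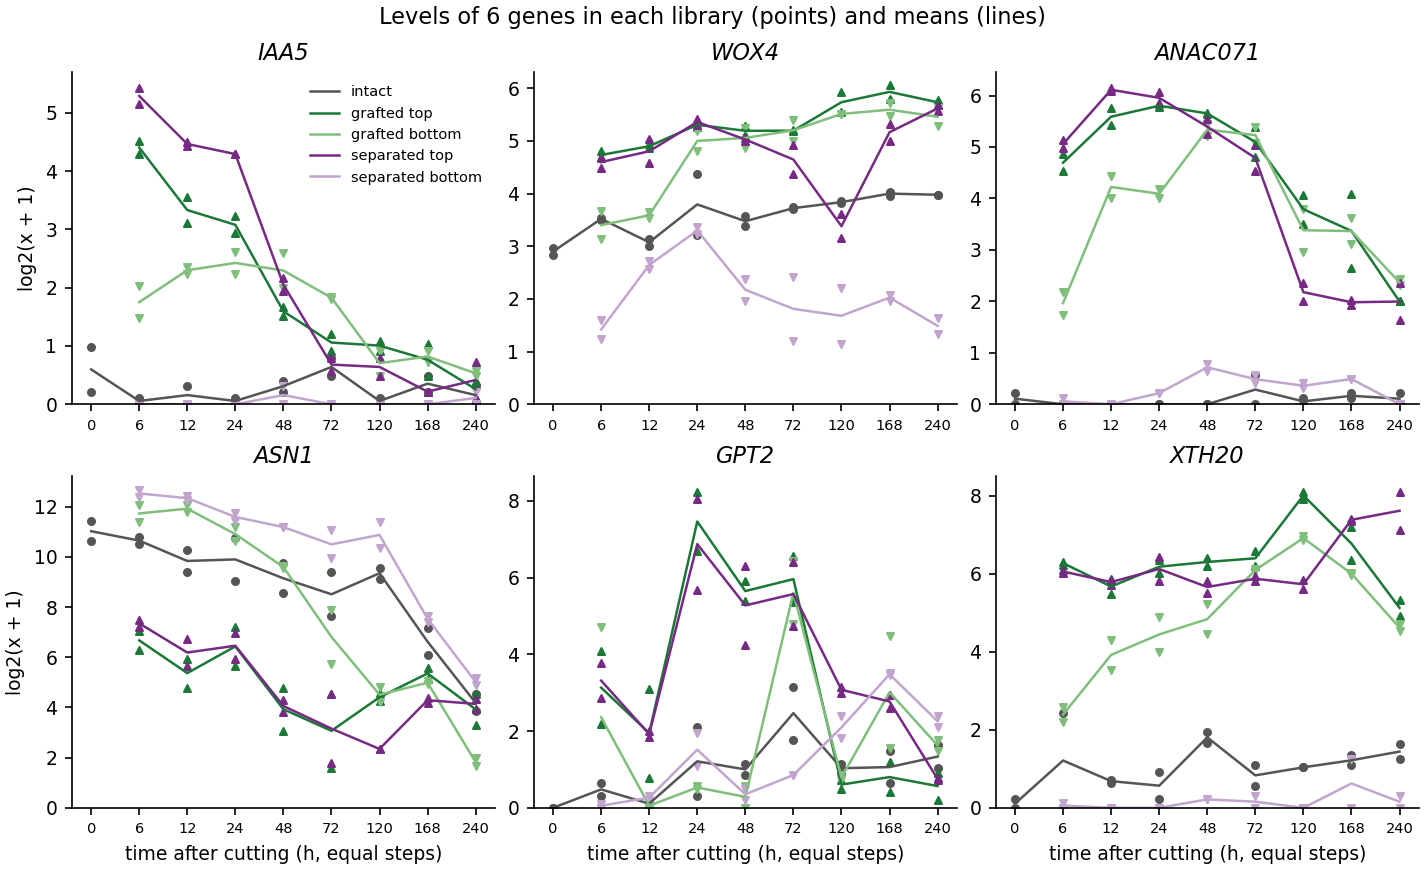
Levels of 6 genes in log2(x + 1) per library (points) with means of 2 libraries (lines) against hours after cutting in equal steps, for the 5 conditions. IAA5, ANAC071 and XTH20 lie near 0 in separated bottoms and above it in grafted bottoms at 12 h, and ASN1 is highest in the bottoms at 6 h.

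Intact hypocotyls at the same times were the control for the response to the operation. Grafted tops differed from them at 12979 genes at 6 to 24 h, 6578 higher and 6401 lower. Wound regeneration genes were among the most raised: ERF115 (6.28 ± 0.18) and PSK5 (AT5G65870, 4.30 ± 0.13) rose, and ANAC071 stood at 42.4 ± 14.4 in grafted tops and was listed at 0 in the 6 intact libraries. The extensins EXT3 (AT1G21310, 7.72 ± 0.22) and EXT4 (AT1G76930, 7.40 ± 0.20) had the largest increases with a known name, and NIA1 (AT1G77760, -5.0 ± 0.21) and the carbonic anhydrase CA2 (AT5G14740, -4.55 ± 0.40) the largest decreases. Among 16 wound regeneration genes, 15 were higher and 1 was not called (median 3.37, adjusted p = 1.5e-10, adjusted p = 0.0061 with estimated correlation). 11 of 12 rapid stress response genes were higher and 1 was not called (median 1.51, adjusted p = 3.8e-05, adjusted p = 0.28 with estimated correlation). Of the 18 cambium genes 14 were higher, 1 was lower and 3 were not called (median 0.87, adjusted p = 1.4e-04, adjusted p = 0.17 with estimated correlation), and among 20 auxin response genes, 13 were higher, 3 were lower and 4 were not called (median 1.36, adjusted p = 7.0e-04, adjusted p = 0.23 with estimated correlation). 19 of 22 sugar starvation genes were lower and 3 were not called (median -1.54, adjusted p = 2.3e-05, adjusted p = 0.45 with estimated correlation). The 26 photosynthesis genes were all lower (median -2.16, adjusted p = 8.6e-14, adjusted p = 0.27 with estimated correlation). In all, 10 of the 23 lists were called. The counts given here, adjusted over the list alone, did not move.

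Late grafted tops, at 120 to 240 h, differed from intact tissue at 11502 genes, 6363 higher and 5139 lower. GRP9 (AT2G05440, 6.62 ± 0.26), CYP706A2 (AT4G22710, 6.58 ± 0.21), MYB15 (AT3G23250, 5.93 ± 0.24) and EXT4 (5.97 ± 0.20) were among the most raised. CYP79F1 (-5.35 ± 0.44) and MYB29 (AT5G07690, -3.65 ± 0.31), genes of aliphatic glucosinolate synthesis and its control, were the lowest with a known name. Of the 16 wound regeneration genes 15 were higher and 1 was lower (median 2.94, adjusted p = 2.3e-11, adjusted p = 0.0039 with estimated correlation), and among 18 cambium genes, 17 were higher and 1 was lower (median 1.70, adjusted p = 7.6e-09, adjusted p = 0.036 with estimated correlation). 28 of 30 xylem and secondary wall genes were higher and 2 were not called (median 1.32, adjusted p = 9.2e-09, adjusted p = 0.085 with estimated correlation), and of the 29 cell cycle genes 28 were higher and 1 was not called (median 1.54, adjusted p = 9.4e-11, adjusted p = 0.13 with estimated correlation). All 26 photosynthesis genes were lower (median -1.68, adjusted p = 1.4e-13, adjusted p = 0.27 with estimated correlation). 9 of the 23 lists were called. Adjusted over the list alone, the member counts given here moved only for xylem and secondary wall (29 higher, 0 lower). The share of higher calls was 55.3%, and 43.5% under quantile normalisation.

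Grafted bottoms differed from intact tissue at 10128 genes at 6 to 24 h, 4230 higher and 5898 lower. Wound and starvation genes were raised together: ERF115 (5.11 ± 0.18) and ASN1 (1.39 ± 0.41) rose. AT5G64120 (8.58 ± 0.29), EXT3 (7.93 ± 0.22) and EARLI1 (AT4G12480, 7.58 ± 0.28) were among the most raised, and CYP83A1 (AT4G13770, -5.28 ± 0.39), an enzyme of glucosinolate synthesis, and GSTU20 (AT1G78370, -4.88 ± 0.38) decreased. Among 16 wound regeneration genes, 15 were higher and 1 was not called (median 2.65, adjusted p = 1.2e-16, adjusted p = 4.3e-04 with estimated correlation). 19 of 22 sugar starvation genes were higher and 3 were not called (median 1.91, adjusted p = 2.0e-09, adjusted p = 0.26 with estimated correlation). Of the 30 xylem and secondary wall genes 26 were lower, 2 were higher and 2 were not called (median -1.2, adjusted p = 2.0e-07, adjusted p = 0.12 with estimated correlation). Among 11 shoot epidermis and guard cell marker genes, 8 were lower, 1 was higher and 2 were not called (median -1.04, adjusted p = 0.0024, adjusted p = 0.26 with estimated correlation), with PDF2 (AT4G04890, -2.29 ± 0.14) and ATML1 (AT4G21750, -1.47 ± 0.13). The lists called were 8 of 23. With adjustment over the list alone, member counts given here moved only for wound regeneration (16 higher, 0 lower) and xylem and secondary wall (2 higher, 28 lower).

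In the later window grafted bottoms and intact tissue differed at 11134 genes, 5277 higher and 5857 lower, and GRP9 (7.59 ± 0.26), MYB15 (6.98 ± 0.24) and WRKY48 (AT5G49520, 6.75 ± 0.16) were among the most raised. The 12 rapid stress response genes were all higher (median 3.80, adjusted p = 2.6e-14, adjusted p = 0.059 with estimated correlation), and 15 of 16 wound regeneration genes were higher and 1 was lower (median 2.64, adjusted p = 1.1e-12, adjusted p = 0.0020 with estimated correlation). Of the 23 jasmonate genes 12 were higher, 1 was lower and 10 were not called (median 1.13, adjusted p = 5.3e-04, adjusted p = 0.41 with estimated correlation), and among 10 salicylic acid and defence genes, 7 were higher and 3 were not called (median 1.26, adjusted p = 0.0041, adjusted p = 0.23 with estimated correlation). All 26 photosynthesis genes were lower (median -1.0, adjusted p = 3.2e-07, adjusted p = 0.47 with estimated correlation), and under quantile normalisation it was not called (adjusted p = 0.28; 5.3e-08 to 0.47 over the alternatives tried). Shoot and root marker lists were both lower: 7 of 11 shoot epidermis and guard cell marker genes were lower and 4 were not called (median -0.91, adjusted p = 0.0043, adjusted p = 0.28 with estimated correlation), and of the 15 root marker genes 7 were lower, 1 was higher and 7 were not called (median -0.34, adjusted p = 0.020, adjusted p = 0.40 with estimated correlation). Member counts given here, adjusted over the list alone, moved only for salicylic acid and defence (8 higher, 0 lower). 12 of the 23 lists were called. The share of higher calls was 47.4%, 37.2% under quantile normalisation and 57.6% under median-of-ratios scaling.

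Separated tops differed from intact tissue at 13036 genes at 6 to 24 h, 6647 higher and 6389 lower. EXT3 (7.84 ± 0.22) and EXT4 (7.53 ± 0.20) were raised, and NIA1 (-5.83 ± 0.21), CA2 (-4.77 ± 0.40) and BT2 (-4.59 ± 0.52) lowered. Among 16 wound regeneration genes, 15 were higher and 1 was not called (median 3.34, adjusted p = 2.7e-10, adjusted p = 0.0066 with estimated correlation). 15 of 20 auxin response genes were higher, 1 was lower and 4 were not called (median 1.93, adjusted p = 6.5e-07, adjusted p = 0.082 with estimated correlation), with IAA5 at 26.0 ± 9.86 against 0.0674 ± 0.0946 in intact tissue. Of the 22 sugar starvation genes 19 were lower and 3 were not called (median -1.47, adjusted p = 1.1e-04, adjusted p = 0.49 with estimated correlation), and the 26 photosynthesis genes were all lower (median -2.25, adjusted p = 3.2e-14, adjusted p = 0.26 with estimated correlation). Among 10 nitrate response genes, 7 were lower, 1 was higher and 2 were not called (median -1.28, adjusted p = 0.0016, adjusted p = 0.21 with estimated correlation). In all, 10 of the 23 lists were called. The counts given here, adjusted over the list alone, did not move.

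For 120 to 240 h the count was 14836 genes, 9290 higher and 5546 lower, and 7965 at 240 h alone, chosen after seeing the data. LHCB2.3 (-7.09 ± 0.32), CA1 (-6.51 ± 0.41) and LHB1B1 (-6.13 ± 0.43) were the lowest with a known name. All 26 photosynthesis genes were lower (median -3.96, adjusted p = 2.7e-20, adjusted p = 0.18 with estimated correlation). 27 of 30 xylem and secondary wall genes were higher, 1 was lower and 2 were not called (median 1.48, adjusted p = 2.0e-04, adjusted p = 0.26 with estimated correlation), and of the 29 cell cycle genes 28 were higher and 1 was not called (median 2.07, adjusted p = 1.5e-08, adjusted p = 0.21 with estimated correlation). Among 11 shoot epidermis and guard cell marker genes, 6 were lower, 3 were higher and 2 were not called (median -0.77, adjusted p = 0.0480, adjusted p = 0.46 with estimated correlation), a call lost under quantile normalisation (adjusted p = 0.089) and median of ratios (adjusted p = 0.0532). 9 of the 23 lists were called. Adjusted over the list alone, the member counts given here did not move. The median of all genes was 0.17, and 0.02 under quantile normalisation. The share of higher calls was 62.6%, and 51.5% under that scaling.

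Separated bottoms differed from intact tissue at 11357 genes at 6 to 24 h, 5054 higher and 6303 lower. Starvation genes were raised and cambium and xylem genes lowered: ASN1 (2.03 ± 0.41), SEN1 (AT4G35770, 3.36 ± 0.38), a dark-induced gene, PXY (-4.2 ± 0.17) and ACL5 (-6.08 ± 0.22). TI1 (AT2G43510, 8.01 ± 0.18) and EXT4 (7.80 ± 0.20) were among the most raised, and CYP83A1 (-6.37 ± 0.39) and GSTU20 (-6.18 ± 0.38) among the lowest. 21 of 22 sugar starvation genes were higher and 1 was not called (median 2.13, adjusted p = 9.5e-10, adjusted p = 0.26 with estimated correlation). Of the 16 wound regeneration genes 13 were higher, 2 were lower and 1 was not called (median 1.69, adjusted p = 1.2e-07, adjusted p = 0.036 with estimated correlation). Among 30 xylem and secondary wall genes, 26 were lower, 2 were higher and 2 were not called (median -1.64, adjusted p = 6.5e-08, adjusted p = 0.10 with estimated correlation), and 13 of 18 cambium genes were lower and 5 were not called (median -1.01, adjusted p = 1.6e-06, adjusted p = 0.082 with estimated correlation). Of the 20 auxin response genes 12 were lower and 8 were not called (median -0.71, adjusted p = 3.4e-04, adjusted p = 0.21 with estimated correlation), and among 11 shoot epidermis and guard cell marker genes, 7 were lower, 1 was higher and 3 were not called (median -1.30, adjusted p = 0.0076, adjusted p = 0.30 with estimated correlation). The lists called were 9 of 23. With adjustment over the list alone, member counts given here moved only for cambium (0 higher, 14 lower), auxin response (0 higher, 13 lower) and shoot epidermis and guard cell markers (2 higher, 7 lower).

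Late separated bottoms, at 120 to 240 h, differed from intact tissue at 13199 genes, 6719 higher and 6480 lower. HIR2 (AT3G01290, 7.51 ± 0.24), NAS3 (7.24 ± 0.21) and the invertase ATBFRUCT1 (AT3G13790, 7.19 ± 0.22) were the most raised with a known name, and MLP43 (AT1G70890, -7.54 ± 0.21) was among the lowest. 16 of 18 cambium genes were lower, 1 was higher and 1 was not called (median -1.98, adjusted p = 5.3e-08, adjusted p = 0.057 with estimated correlation), and of the 20 auxin response genes 14 were lower and 6 were not called (median -2.02, adjusted p = 2.3e-06, adjusted p = 0.092 with estimated correlation). Among 22 sugar starvation genes, 17 were higher, 1 was lower and 4 were not called (median 1.44, adjusted p = 1.1e-04, adjusted p = 0.49 with estimated correlation). 8 of 11 cytokinin response genes were higher and 3 were not called (median 1.48, adjusted p = 0.0018, adjusted p = 0.21 with estimated correlation). Of the 16 wound regeneration genes 10 were higher, 3 were lower and 3 were not called (median 1.09, adjusted p = 0.0066, adjusted p = 0.26 with estimated correlation), with RAP2.6L (6.45 ± 0.18) and WIND1 (AT1G78080, 1.58 ± 0.10). Among 26 photosynthesis genes, 16 were higher and 10 were not called (median 0.65, adjusted p = 0.017, adjusted p = 0.75 with estimated correlation), a direction that flipped under quantile normalisation to a median of -0.015, with adjusted p = 0.93 and 0.0094 to 0.93 over the alternatives. Root markers fell with the vascular groups: 8 of 15 root marker genes were lower and 7 were not called (median -2.56, adjusted p = 6.7e-05, adjusted p = 0.16 with estimated correlation), with CASP1 (-7.13 ± 0.22). Member counts given here, adjusted over the list alone, did not move. 10 of the 23 lists were called.

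Intact hypocotyls themselves changed over time. Age and the time since 1 cotyledon was taken off run together in this comparison. Against 0 h, intact tissue at 120 to 240 h differed at 9203 genes, 4548 higher and 4655 lower, with 2 libraries at 0 h. CASP1 (7.45 ± 0.30) and the laccase LAC3 (AT2G30210, 7.20 ± 0.36) were the most raised with a known name, and PDF1 (-8.39 ± 0.38) and XTH15 (AT4G14130, -5.46 ± 0.30) the most lowered. ASN1 (-4.31 ± 0.59) and SEN1 (-4.38 ± 0.54) fell, as did XTH19 (AT4G30290, -3.26 ± 0.49), and APL3 (2.91 ± 0.46) rose. With 1 library left out the count was 6535 to 8949, the lowest without replicate 2 of the intact group at 0 h.

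In the TAIR10.1 reference annotation these named genes lie at IAA5 on chromosome 1 (5365512 to 5366497, minus strand, 3 exons), PXY on chromosome 5 (24724337 to 24728244, minus strand, 2 exons) and ASN1 on chromosome 3 (17437840 to 17441431, minus strand, 5 to 10 exons). The values are per gene, and the deposited tables hold no coordinates.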

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

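The tests of library scaling, of a batch between times and of tissue of the other part in late grafted samples were chosen only after the result was seen. The top-bottom difference differed between grafted and separated plants, by a test of the difference itself, at 4572 genes at 6 to 24 h and at 14463 genes at 120 to 240 h.

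At 6 to 24 h the lead of tops in auxin response and cambium genes was smaller in grafted plants, with medians of -2.43 and -1.48. Top tissue carried into grafted bottoms would give top-higher genes 1 common share of the top level. Genes at x of 5 or more in grafted tops and 4-fold or more over separated bottoms were used. The median share was 47.0% for 22 auxin response and cambium genes, the pattern's own lists, and 4.84% for 12 sugar-induced genes. It was 22.0% for 1108 others (permutation p = 4.0e-05, genes taken as independent). Library scaling is argued against by a median of -2.41 under the scaling that brings the auxin list closest to 0, and unequal depth by -2.39 with all libraries thinned to 7.55 M reads. A smaller share of top tissue in grafted bottoms stays open. A signal that crosses the junction, such as auxin, may account for the rest, a hypothesis that the design names only through joining and that was found and tested on the same data.

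The difference between grafted parts shrank from 48 to 72 h and that between separated parts did not, though grafted parts still differed at 5490 genes at 72 h and at 4904 over 120 to 240 h. Over that step the distance went to 28.2% of its value in grafted (28.3% at equal depth) and 102% in separated plants. This cannot test a batch shared by a time, which cancels in top minus bottom. Tissue of the other part in late grafted samples stays open. The share of starvation transcripts in grafted tops, a median of 3.32% of the way from separated tops to separated bottoms (10 genes, -14.9 to 55.0%), decides nothing, since none of the 10 was 4-fold higher in grafted bottoms than in separated tops and such tissue had little of them to bring. Of 3721 called genes with a mean x of at least 5 in grafted tops at 120 to 240 h, 28 stood in grafted bottoms below 12.5% of that level and 43 below 25%, and 26 and 29 of these were under x of 1 in a grafted top library. The other 14 below 25%, a few extreme genes, argue against a share of top tissue in grafted bottoms above 25% and leave a smaller one open. Joining itself, which the design names, stays open beside it.

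For each of 18 comparisons 100 splits of the libraries were drawn within times, the real one included. For 17 of them 1 split, the real one, was as large. That is the smallest share that 100 splits can give, without adjustment over the 18 comparisons. It makes a chance split unlikely for each and does not exclude it. The highest other counts at 6 to 24 and 120 to 240 h were 10854 and 2961 for grafted parts (real 13462 and 4904), 13065 and 14870 for separated parts (14960 and 16529), 26 and 9381 for tops (72 and 10230), and 6399 and 12398 for bottoms (7189 and 14582). Against intact tissue they were 10210 and 9159 for grafted tops (12979 and 11502), 7881 and 8323 for grafted bottoms (10128 and 11134), 10343 and 13190 for separated tops (13036 and 14836), and 8588 and 10382 for separated bottoms (11357 and 13199). The late difference of differences gave 11866 (14463). Its early form gave 4642 against the real 4572, so 2 of 100 splits were as large, and that other split mixed only the tops, at 2 times. In the 16 comparisons of 2 conditions the highest other split kept the real grouping at 2 of 3 times, a split and its mirror image being 1 split. Of the 32 splits of grafted parts that also part all same-numbered pairs, the highest others gave 10767 and 2327.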

How the results depend on the processing

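Counts of called genes in the windows stayed within 1.5 times under the alternatives tried, including voom weights (chosen after seeing the data), except those given here, and so did 247 counts with 1 library left out, all but 1. The cause of the shifts was not tested unless stated. A planned count test was not run, since whole reads could not be recovered. At single times 2 libraries a side were compared.

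Grafted against separated tops at 6 to 24 h gave 72 genes, and 41, 43 and 44 to 71 under the settings given above. At 240 h alone, chosen after seeing the data, the late difference of differences fell from 14463 to 8996 (12832 at 120 h). Grafted against separated tops fell from 10230 to 1269 (10206) and separated tops against intact from 14836 to 7965 (13938). With a pseudocount of 4, which shrinks low genes, counts of at least 2-fold fell from 578 to 281 for late grafted parts, from 1374 to 719 for the early difference of differences, from 23 to 6 and from 2159 to 1217 for early and late grafted against separated tops, from 1230 to 641 for early bottoms, from 3754 to 2345 for late grafted tops against intact, and from 2855 to 1880 and from 3162 to 1975 for grafted bottoms against intact. A pseudocount of 0.25 raised 578 to 1031 and 1230 to 1909. With voom they were 1378, 35, 3329 and 2102 for late grafted parts, early and late tops, and early bottoms, and with only the compared libraries early tops had 14.

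For grafted against separated tops at single times, 6 genes at 6 h became 23 with a pseudocount of 4 and 28 without the filter. The 11 at 12 h became 30, 29, 7 (median of ratios) and 6 (quantile), the 33 at 24 h became 14 (pseudocount 0.25), 56 (4) and 50 (no filter), and the 250 at 48 h became 376 (quantile). The overlap of 38 genes was 19 with a pseudocount of 0.25. The distance between parts moved with the pseudocount, at 0.25 and 4 in turn: grafted 48 h 0.97 to 1.07 and 0.76, separated 48 h 1.95 to 2.2 and 1.52, grafted 72 h 0.27 to 0.30 and 0.21, separated 72 h 1.99 to 2.24 and 1.54, and separated 240 h 0.99 to 1.11 and 0.74. Grafted 240 h went from 0.059 to 0.044 at 4. Without the filter separated 48 h was 1.91 and grafted 72 h 0.25. Under median of ratios separated 48 h was 1.94, and under quantile normalisation it was 1.88 and separated 240 h 0.88.

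Of 184 list calls 14 passed with an estimated correlation, 188 under quantile normalisation, 180 under median of ratios and 190 with the replicate block. Under quantile normalisation 12 calls were lost, 18 gained and 2 more ended with medians near 0: photosynthesis in the early difference of differences (0.29 to 0.0047, adjusted p = 0.96) and in late separated bottoms against intact (0.65 to -0.015, adjusted p = 0.93).

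Outside grafted tops and bottoms, for none of 9 other pairs of conditions did deviations correlate above 0.1 at all 8 times. Yet 56 of all 80 values did (median 0.139, against 0.002 in 740 pairs across times). At 72 h all did (0.192 to 0.494). The main fit has no block. With the replicate number as a replicate block within times, grafted parts gave 1418 in place of 927 genes at 168 h and 935 in place of 566 at 240 h, grafted against separated tops 22, 54 and 456 at 12, 24 and 48 h, and the separated distance at 48 h 1.92. Window counts under either block stayed within 1.5 times, and for grafted parts no list call or named gene call changed.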

Other observations

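Lists of phosphate starvation, drought and low oxygen genes were called in late separated tops, though not there alone. At 120 to 240 h of the 10 phosphate starvation genes 9 were higher and 1 was lower (median 3.49, adjusted p = 0.0059, adjusted p = 0.37 with estimated correlation) in separated tops against separated bottoms, with PS2 (AT1G73010, 7.44 ± 0.23) and IPS1 (AT3G09922, 1.86 ± 0.10), and among 10 phosphate starvation genes, 8 were lower and 2 were not called (median -1.46, adjusted p = 0.0017, adjusted p = 0.29 with estimated correlation) in grafted against separated tops. 14 of 18 abscisic acid and drought genes were higher, 1 was lower and 3 were not called (median 1.81, adjusted p = 0.016, adjusted p = 0.41 with estimated correlation) between the separated parts, with RD29A (AT5G52310, 4.96 ± 0.35) and the abscisic acid synthesis gene NCED3 (AT3G14440, 3.53 ± 0.24), and of the 18 abscisic acid and drought genes 11 were lower, 1 was higher and 6 were not called (median -0.61, adjusted p = 0.021, adjusted p = 0.43 with estimated correlation) in grafted against separated tops. Among 12 hypoxia genes, 10 were lower and 2 were not called (median -0.81, adjusted p = 8.7e-04, adjusted p = 0.065 with estimated correlation), and against intact tissue 10 of 12 hypoxia genes were higher and 2 were not called (median 1.55, adjusted p = 0.0029, adjusted p = 0.083 with estimated correlation) in separated tops. ADH1 (AT1G77120), alcohol dehydrogenase, stood at 15.7 ± 3.70 in separated tops, 6.47 ± 1.98 in grafted tops and 3.06 ± 1.5 in intact tissue at that stage. Phosphate starvation was also called higher against intact tissue in late grafted tops (median 1.42, adjusted p = 0.030, adjusted p = 0.48 with estimated correlation) and grafted bottoms (median 1.51, adjusted p = 0.015, adjusted p = 0.42 with estimated correlation), and hypoxia in grafted tops (median 0.70, adjusted p = 0.029, adjusted p = 0.21 with estimated correlation), a call lost under quantile normalisation (adjusted p = 0.28). The hypoxia call between separated parts (adjusted p = 0.042) was lost there too (adjusted p = 0.21), and the drought list was not called in separated tops against intact tissue (adjusted p = 0.097). Adjusted over the list alone, these counts moved only for hypoxia in separated top against intact (11 higher, 0 lower).

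The genes THAS1 (7.92 ± 0.26), CYP705A5 (7.47 ± 0.23) and CYP708A2 (AT5G48000, 6.86 ± 0.29) of the thalianol pathway, a root triterpene, were higher in separated tops than in intact tissue at 120 to 240 h, and no list of that pathway was tested. The root marker list was not called in that comparison (median -0.53, adjusted p = 0.90).

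The test that sets the auxin difference against the sugar difference was chosen only after the result was seen. If auxin leaves a grafted top for the bottom, auxin response genes lower in grafted than in separated tops are to be higher in grafted bottoms. 7 of the 9 such genes were. But 13 of the 20 list genes were too, so this cannot decide whether auxin crosses the junction, still a hypothesis. The auxin difference narrowed sooner than the sugar difference. At 6, 12, 24 and 48 h the median top-bottom difference left in grafts was 38.4, 27.3, 22.6 and 11.8% of that in separated plants for auxin response genes and 105, 97.0, 85.3 and 67.7% for sugar starvation genes, with quartiles apart at 4 of 4 times. A permutation test at 48 h (16 and 21 genes, 100000 resamples, 2-sided p = 1.9e-04) was prompted by these values and takes genes as independent. At 72 h the shares were 13.6% and 27.5%. At 120, 168 and 240 h the order was the other way, with 15.5, 22.7 and 18.5% left for auxin response and -0.64, -8.26 and -4.24% for sugar starvation genes. These late shares rest on 15, 13 and 13 auxin response genes and on 18, 12 and 11 sugar starvation genes.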
